A study of Homo sapiens with 4 samples.

How the data were processed

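Gene expression was measured by RNA-seq of poly(A) RNA in 4 libraries of IMR90 cells, a human lung fibroblast line, with 1 library in each of 4 groups. The groups, taken from the sample labels, were growing cells carrying an empty retroviral vector (day 13), cells in oncogene-induced senescence (OIS) after 8 days of 10 nM tamoxifen on an ER:H-RasV12 fusion, and cells given a Flag-tagged, cleaved form of histone H3.3 (H3.3cs1) at an early (day 3) and a late (day 13) time. All were at passage 16.

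The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per locus and library, and the submitters' processing notes name TopHat2 2.0.3, Bowtie2, Cufflinks 2.1.1 and the hg19 build without giving their role or order. Counts of reads, the handling of strand, the handling of reads that map to several places and any normalization between libraries are not given in the sources used here. The deposited files list 26468 loci with gene symbols and a locus number, and no coordinates. The reference annotation at hand is of another build, so no position is printed. Because no counts were at hand and each group has 1 library, no test was made and no p-value, SD or standard error is given.

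Of the loci, 2310 carry no gene name and hold between 47.4% and 57.9% of the summed FPKM of a library. They were left out of all gene comparisons. Another 822 named loci join several genes and were kept under their joined names, such as BBS7,CCNA2. A symbol on several lines (540 symbols on 2019 lines) was given the sum of its lines. XIST and Y-linked genes were left out, which left 22598 symbols. The comparisons used the 12182 of them with an FPKM of at least 1 in at least 1 library.

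Values were compared as log2(FPKM + 1), and every fold is on that scale, which understates the change of genes with low values. A gene was counted as higher or lower, and is said to have risen or fallen, when its difference was at least 2-fold. A gene listed at 0 can be a failed estimate, so no fold is given against such a value. Lists of genes (26 lists) were fixed before the data were examined, as were the comparisons, the size rule, the rule for named genes and 7 processing alternatives. For each list the median difference of its members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lies below percentile 2.5 or above percentile 97.5 of its random lists, as a description of these libraries and not a test of the conditions. The list of mitochondrially encoded genes had no locus of such a name and gave no value.

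The lists cover mitosis, DNA replication and E2F targets, CDK inhibitors and the RB family, p53 targets, cytokines and chemokines of the senescence-associated secretory phenotype (SASP), matrix proteases and their inhibitors, IGF binding proteins and growth factors, RAS and MAPK output, extracellular matrix, contractile genes, fibroblast identity, interferon-stimulated genes, lysosome and autophagy, H3.3 genes and chaperones, replication-dependent histones, nuclear lamina and heterochromatin, Polycomb, cholesterol synthesis, the unfolded protein and integrated stress response, immediate early genes, ribosomal protein genes, housekeeping genes, mitochondrially encoded genes, and markers of epithelial, endothelial and leukocyte cells. Named genes were HRAS, H3F3A, H3F3B and the cathepsin L gene, the 8 largest rises and 8 largest falls against growing (5 and 5 in the other comparisons) among genes above 0 in both libraries and at FPKM of at least 5 in the higher, leaving out short and uncharacterised RNAs, up to 4 members of each list with the largest differences, the 10 genes with the largest shared rises and falls in OIS and H3.3cs1 late, up to 5 genes with opposite differences in each direction, and CDKN1A, CDKN2A, CDKN2B, RB1, CCNA2, LMNB1, IL6 and IL8. Some genes outside this rule are also named, such as PLEC, ATP13A3 and PECAM1, and not all of them are marked.

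OIS and H3.3cs1 late were both compared with the growing library, so their differences share its chance values. The overlap and correlation were set beside 100 simulated pairs of unchanged groups against a shared control, with noise taken from the closest pair of libraries (growing and H3.3cs1 early), and beside the overlap of independent lists of the same sizes. That noise includes any real change between those libraries. A relation with no shared library (OIS minus growing against H3.3cs1 late minus H3.3cs1 early) was also computed. It leaves out differences from growing that were present at day 3, so it is a different measure.

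The size rule and the list percentiles were checked on simulated data made from the growing profile over 12182 genes with the same noise. Of the changed genes at FPKM of at least 5, 62.5% of those changed by 2.5-fold and 100% of those changed by 4, 8 or 16-fold were recovered with the right sign, and 0.317% of the 11982 unchanged genes were counted as changed. Of 200 random lists, 2% stood apart. The simulated noise leaves out extreme values and values wrongly listed at 0, so 0.317% can be lower than the share in real libraries. Genes were simulated independently, and random lists placed among random lists seldom stand apart by definition. The share of 2% is therefore no error rate for the fixed lists.

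The number of reads per library is unknown. At values below 0.1 FPKM, the value of 1 fragment in OIS, H3.3cs1 early and H3.3cs1 late was estimated at 1.20, 1.04 and 1.29 times that in growing, which puts their depth at about 83.2%, 95.9% and 77.6% of the growing library. These estimates rest on a peak with 145 of 1151, 291 of 1392 and 88 of 1233 low loci close to it, so that of late is weak. They also hold only if the values were not normalized between libraries, which is unknown. Alternatives were a pseudocount of 0.1, no filter, a filter at FPKM of 5, rescaling the named genes to the same sum, centring on the median log2 ratio over genes at FPKM of at least 1 in all 4 libraries, quantile normalization, and leaving out genes at 0 in any library. Keeping the highest line per symbol and leaving out joined loci were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.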

Results

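The transcriptomes of 4 IMR90 fibroblast cultures were compared to ask how the cleaved form of the replacement histone H3.3 changes gene expression, and how far that resembles senescence driven by oncogenic RAS. There was 1 library each of growing cells with an empty vector, cells in OIS after activation of ER:H-RasV12, and cells with H3.3cs1 at day 3 (early) and day 13 (late). There are no replicates, so each difference describes these libraries and has no replicate check. Between 11062 and 11270 genes per library reached an FPKM of 1. Depth relative to the growing library was estimated at 83.2% for OIS, 95.9% for H3.3cs1 early and 77.6% for H3.3cs1 late. These estimates are rough, and that of late is weak.

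Between 63 and 87 of the 12182 compared genes were listed at 0 in a library. PLEC, which encodes the cytoskeletal linker plectin, was listed at 128 FPKM in growing, 0 in OIS, 0 in H3.3cs1 early and 133 in H3.3cs1 late, so a value of 0 is not read as absence. Median differences over all genes were 0.032 for OIS, -0.025 for H3.3cs1 early and -0.040 for H3.3cs1 late against growing. After rescaling the named genes of each library to the same sum they were -0.18, 0.21 and -0.026, and the splits of higher and lower genes that moved with this shift are given beside the counts.

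HRAS matched the label of OIS, the group with the ER:H-RasV12 fusion. HRAS stood at 3153 FPKM in OIS against 47.4 in growing, 49.8 in H3.3cs1 early and 41.9 in H3.3cs1 late. H3F3B, one of the genes that encode H3.3, rose from 105 FPKM in growing to 229 in H3.3cs1 early and 450 in H3.3cs1 late, with 90.5 in OIS. FPKM per gene does not separate a construct's transcript from that of the endogenous gene. The labels do not say which H3.3 gene the H3.3cs1 construct holds, so the rise of H3F3B is not a check of them. H3F3A, the other H3.3 gene, was at 190, 236, 130 and 132 FPKM in growing, OIS, early and late. CTSL1, the gene of cathepsin L, a protease known to cleave histone H3, was at 68.1, 101, 66.4 and 57.8 FPKM in the same order, with no difference of 2-fold.

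**Figure D1:**
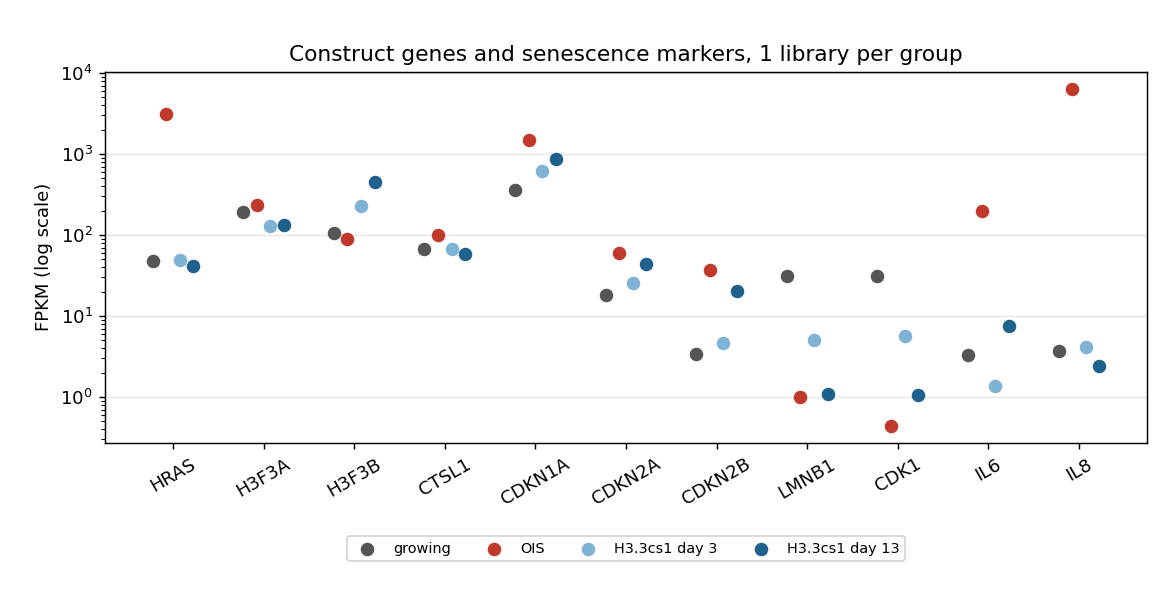
FPKM on a log axis for HRAS, the H3.3 genes H3F3A and H3F3B, cathepsin L and senescence markers, with 1 point per library of growing, OIS, H3.3cs1 early (day 3) and H3.3cs1 late (day 13) cells. Which H3.3 gene the H3.3cs1 construct holds is not given. HRAS and IL8 are far above the other libraries only in OIS, at 3153 and 6433 FPKM, and LMNB1 and CDK1 are lowest in OIS and H3.3cs1 late.

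In OIS, 19 of 22 SASP cytokines and chemokines rose, some to very high levels, while all 34 mitosis genes fell. IL8, a neutrophil-attracting chemokine, rose 1385-fold to 6433 FPKM, IL1B, an inflammatory cytokine, rose 1048-fold to 2869 FPKM, and MMP3, the matrix protease stromelysin, rose 582-fold to 2226 FPKM. The growth factors CSF2 (402-fold) and CSF3 (268-fold) and the chemokines CXCL5 (396-fold), CXCL1 (354-fold) and CXCL3 (273-fold) completed the 8 largest rises. The largest falls were those of PLK1 (35.5-fold), a mitotic kinase, CDC20 (35.2-fold), an activator of the anaphase-promoting complex, ANLN (31.5-fold), a cytokinesis protein, and UBE2C (31.5-fold), a ubiquitin-conjugating enzyme of mitotic exit. KISS1 (27.1-fold), KIF20A (24.1-fold), the chemokine CXCL12 (22.6-fold) and CDK1 (22.4-fold), the kinase that drives entry into mitosis, followed.

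By list, 19 of 22 SASP cytokines and chemokines rose, with a median difference of 5.54 (percentile 100). CCL2, at 76.1 FPKM in growing and 57.1 in OIS, CCL5 and CCL26 did not pass 2-fold. Of 16 matrix proteases and inhibitors 10 rose and 1 fell (median 2.05), with MMP3, SERPINB2 (74.7-fold), a protease inhibitor, MMP10 (66.3-fold) and MMP12 (20.4-fold) in the lead. RAS and MAPK output had a median of 1.87 with 10 of 16 members higher, among them DUSP6 (13.6-fold), a phosphatase that acts on ERK. Immediate early genes had 10 of 14 members higher (median 1.47), led by FOS (10.9-fold) and FOSB (9.79-fold), which encode AP-1 subunits. All 3 lists stood at percentile 100. IGF binding proteins and growth factors went both ways, with 9 of 20 higher and 3 lower (median 0.73), from EREG (75.6-fold) and AREG (64.2-fold), ligands of the EGF receptor, to IGFBP3, which fell 5.96-fold.

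All 34 mitosis genes fell in OIS (median -3.80), as did 33 of 35 DNA replication and E2F targets (median -1.99), with TK1 (20.8-fold) and RRM2 (13.4-fold), enzymes of nucleotide supply, in front. LMNB1, the lamin B1 gene, fell 16.0-fold to 0.989 FPKM, and 9 of 18 nuclear lamina and heterochromatin genes fell (median -1.04). Extracellular matrix genes had 12 of 23 members lower and 2 higher (median -1.12). LOX, a collagen cross-linking enzyme, fell 7.02-fold, DCN, the proteoglycan decorin, fell 5.47-fold and COL1A1 fell 4.10-fold, while POSTN, a matricellular protein, rose 18.9-fold. Of 11 contractile genes 8 fell (median -1.53), with TAGLN (13.5-fold), LMOD1 (10.1-fold), CNN1 (8.91-fold) and ACTG2 (7.24-fold) furthest, and TGFBI, a matrix protein on that list, rose. Fibroblast identity genes had 6 of 14 lower (median -0.58).

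Among cell cycle inhibitors, CDKN1A (p21) rose from 363 to 1500 FPKM, CDKN2A (the p16 and ARF locus) from 18.1 to 59.8 and CDKN2B (p15) from 3.43 to 37.3. CDKN2C (p18) fell 8.89-fold and the list of 10 as a whole did not stand apart (median 0.40), though it did with a filter at FPKM of 5 (0.63). RB1 was at 11.3 FPKM in growing and 13.8 in OIS, and the joined BBS7,CCNA2 locus, which holds cyclin A2, fell from 34.8 to 8.81. IL6 rose 46.2-fold. Cholesterol synthesis genes had a median of 0.66 with 4 of 18 higher and 1 lower. Of 10 endothelial markers, 4 reached an FPKM of 1 in at least 1 library. Of these 3 rose in OIS (median 1.475), CLDN5 to 11.6 FPKM, TIE1 to 4.05 and ROBO4 to 4.47. That filter counts OIS, so a marker high only there is kept while one low in every library is not. PECAM1, another endothelial gene, was at 0.115 FPKM in OIS, and CDH5 and KDR were listed at 0, which is not read as absence. In all, 1112 genes were at least 2-fold higher and 995 lower in OIS, so 52.8% of the changed genes were higher. That share was 36.9% after rescaling to the same sum, 49.0% after centring and 48.9% with a pseudocount of 0.1, so which direction prevailed depended on the processing. A fall by 8-fold or more was seen for 114 genes and a rise of that size for 131. Of the changed genes 74 were listed at 0 in one of both libraries. OIS also differed from growing in vector, tamoxifen and culture times, which these libraries do not separate.

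**Figure D2:**
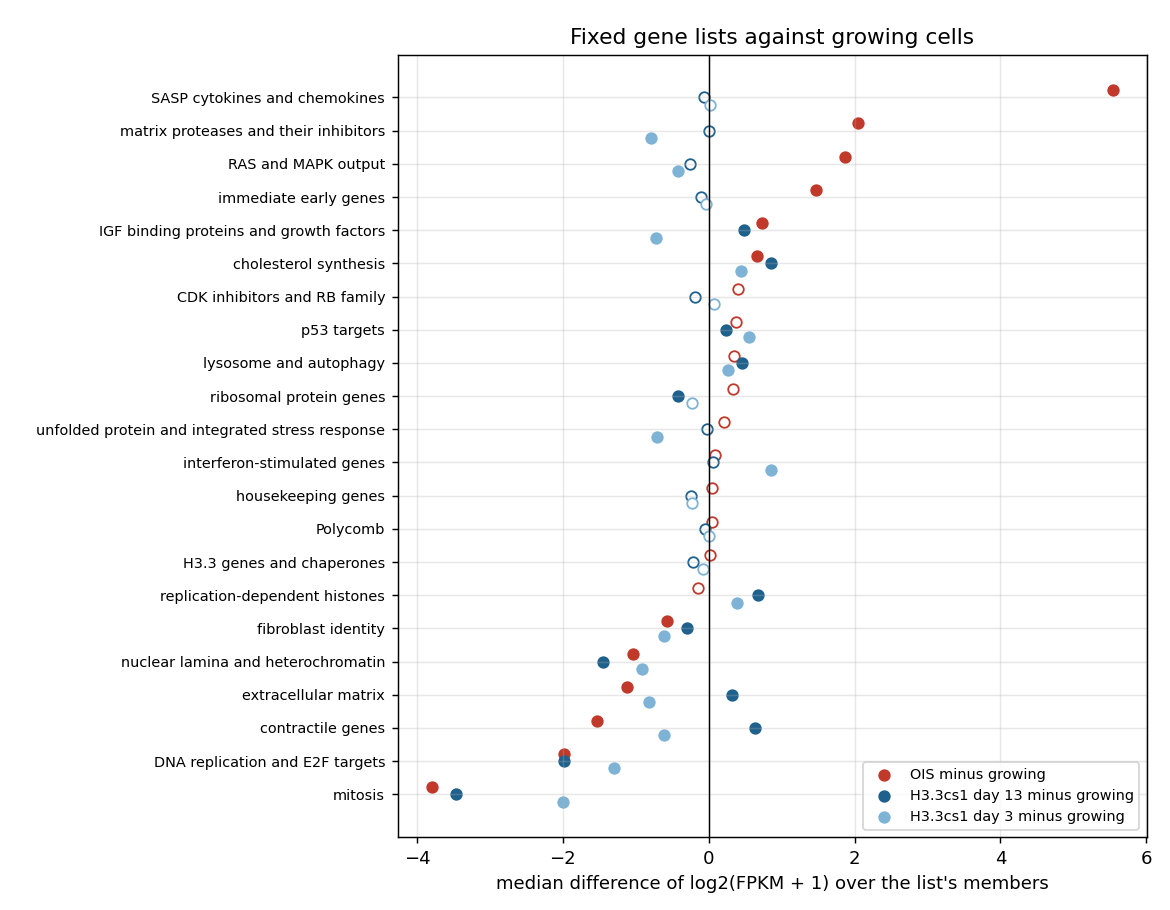
Median difference of log2(FPKM + 1) from the growing library over the members of the fixed gene lists, for OIS, H3.3cs1 late (day 13) and H3.3cs1 early (day 3). The epithelial, endothelial, leukocyte and mitochondrially encoded lists, with few or no members at an FPKM of at least 1 in a library, are not drawn. Filled points are lists that stand apart from random lists matched on expression and open points are those that do not. The SASP list is at 5.54 in OIS and near 0 in both H3.3cs1 libraries, while mitosis is at -3.80, -3.46 and -2.003.

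In H3.3cs1 late cells, all 34 mitosis genes fell as they did in OIS, while 1 of 22 SASP genes rose and 1 fell, and the medians of the matrix and contractile lists lay above the growing level. ANKRD1, a cardiac ankyrin repeat protein, rose 15.0-fold to 135 FPKM, NPPB, a natriuretic peptide precursor, rose 13.3-fold, CCND2, cyclin D2, rose 10.9-fold and TGFB2, a TGF-beta ligand, rose 9.28-fold. CRYAB (8.03-fold), a small heat shock protein, ITGA11 (7.94-fold), a collagen receptor subunit, SH2D4A (7.77-fold) and a locus joining SNHG12 with small nucleolar RNAs (12.1-fold) were the other leading rises. The value of that joined locus cannot be read as that of SNHG12. The falls included UBE2C (21.0-fold), CDC20 (19.3-fold), TOP2A (18.7-fold), RRM2 (18.6-fold), PLK1 (17.0-fold), CDK1 (15.6-fold) and KIF20A (15.3-fold). The joined NRF1,RNA5SP244 locus was at 233 FPKM in growing, 400.2 in OIS, 2.64 in early and 3.32 in late, and it holds a 5S RNA pseudogene, so its value cannot be read as that of NRF1.

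All 34 mitosis genes fell (median -3.46), as did 33 of 35 DNA replication and E2F targets (median -1.99) and 13 of 18 lamina and heterochromatin genes (median -1.45). LMNB1 fell 15.2-fold to 1.09 FPKM, HMGB2, a chromatin protein, fell 9.12-fold and TMPO, a lamina-associated protein, fell 6.23-fold. CDKN1A rose 2.36-fold to 859 FPKM, CDKN2A rose 2.33-fold and CDKN2B rose 4.86-fold, while CDKN2C fell 9.02-fold. RB1 stood at 7.86 FPKM, and the BBS7,CCNA2 locus fell to 6.98. The inhibitor list as a whole did not stand apart (median -0.19).

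Of the 22 SASP cytokines and chemokines 1 rose and 1 fell in H3.3cs1 late (median -0.064, percentile 35.4). IL6, at 7.54 FPKM against 3.26 in growing, was the member that rose, by 2.002-fold (just under 2-fold with the highest of its lines in place of their sum), and TNFAIP3, an inhibitor of NF-kappaB signalling, the one that fell (2.26-fold). IL8 was at 2.40 FPKM. Members such as IL1A (0.063 FPKM in growing, 0.022 in late) and CSF3 (0.183 and 0.137) entered the comparison through OIS. Between values below 1 FPKM no 2-fold difference is possible on this scale, so such members hold the median near 0. The percentile is limited too, because the random lists were matched on a mean that includes OIS. With a pseudocount of 0.1 the median was -0.27 (percentile 4.76). Matrix proteases had 2 of 16 higher and 3 lower (median -0.0021, and 0.036 after centring), and RAS and MAPK output had 0 of 16 higher and 3 lower (median -0.26). The last list did not stand apart, but did after rescaling to the same sum (-0.27), with genes at 0 left out (-0.26) and with joined loci left out (-0.35). Immediate early genes had a median of -0.11 with 1 of 14 lower.

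Extracellular matrix genes had a median of 0.32 (percentile 99.8) with 2 of 23 higher and 1 lower. LUM, a collagen-binding proteoglycan, rose 3.86-fold, POSTN rose 2.96-fold and COL6A3, a collagen VI chain, fell 4.67-fold. All 11 contractile genes lay above 0 (median 0.63) and 4 passed 2-fold, CNN1 (2.76-fold), LMOD1 (2.19-fold), TGFBI (2.15-fold) and TPM1 (2.08-fold). IGF binding proteins and growth factors had 7 of 20 higher and 1 lower (median 0.49), led by TGFB2, IGFBP7 (5.72-fold) and IGFBP2 (5.16-fold), with a 4.52-fold fall of STC1. Replication-dependent histone genes had 12 of 31 higher and 0 lower (median 0.68, percentile 100), led by HIST1H4H (5.79-fold), HIST1H1C (5.67-fold) and HIST1H2BC (4.16-fold). Histone genes are near-identical copies, so how fragments were divided among them is uncertain. Cholesterol synthesis genes (median 0.85, 3 of 18 higher, 18 above 0) and lysosome and autophagy genes (median 0.46, 3 of 22 higher) also stood apart, with MSMO1 (2.41-fold) and FUCA1 (3.18-fold), a lysosomal fucosidase, furthest. Ribosomal protein genes had a median of -0.43 with none of 24 past 2-fold. Of p53 targets 3 of 17 rose (median 0.23), GDF15 3.09-fold among them.

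In all, 428 genes were at least 2-fold higher and 667 lower in H3.3cs1 late, and 47 of them were listed at 0 in one of both libraries. Of the changed genes 39.1% were higher, and 43.6% were after rescaling to the same sum. ATP13A3 was listed at 38.3 FPKM in growing, 185 in OIS, 38.5 in early and 0 in late.

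At day 3 of H3.3cs1, most division genes were lower than in growing cells of day 13, and 7 of 17 interferon-stimulated genes were higher. The medians of the matrix, contractile and growth factor lists lay below the growing level. All 34 mitosis genes fell (median -2.003), PLK1 by 5.91-fold and CDC20 by 5.81-fold, and 27 of 35 replication genes fell (median -1.29). HMOX1, heme oxygenase 1, rose 5.07-fold to 69.0 FPKM, QPRT, an enzyme of NAD synthesis, rose 5.91-fold, CRABP2, a retinoic acid binding protein, rose 5.21-fold and THBS2, thrombospondin 2, rose 4.73-fold. GJA9-MYCBP (7.84-fold), FOLR3 (6.26-fold), SBSN (5.54-fold) and CERS4 (4.73-fold) were the other leading rises. Besides the NRF1,RNA5SP244 locus, the falls were led by the joined METTL12,SNORA57 locus (13.0-fold), KISS1 (11.5-fold), the joined IGF2,INS,INS-IGF2 locus (9.70-fold), SCUBE3 (8.35-fold), IGFBP3 (8.07-fold), MMP1 (7.73-fold), the interstitial collagenase, and TNFRSF11B (6.68-fold), osteoprotegerin. The METTL12,SNORA57 locus holds a small nucleolar RNA, so its value cannot be read as that of METTL12.

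Of 17 interferon-stimulated genes 7 rose and 0 fell at day 3 (median 0.86, percentile 100), with IFIT1 at 4.67 FPKM against 0.703 (3.33-fold), MX1 at 2.79 against 0.158 (3.28-fold), IFI6 at 52.1 against 16.4 (3.05-fold) and IFIT2 (3.03-fold). Of p53 targets 2 of 17 rose (median 0.56), BTG2 (2.84-fold) and TP53INP1 (2.48-fold). Of 20 IGF binding proteins and growth factors 9 fell (median -0.72). Matrix proteases had 6 of 16 lower (median -0.79), with PLAT (4.75-fold) and PLAU (4.01-fold), the plasminogen activators, after MMP1. Extracellular matrix genes had 6 of 23 lower (median -0.82), with DCN (2.93-fold), SPARC (2.59-fold) and LOXL2 (2.49-fold) furthest. The contractile list (median -0.61) had 1 of 11 lower, ACTA2, smooth muscle actin (3.06-fold). The unfolded protein and integrated stress response list (median -0.70) had 2 of 16 lower, CHAC1 (3.74-fold) and ASNS (2.56-fold). Lamina and heterochromatin genes had 6 of 18 lower (median -0.92), with LMNB1 at 5.03 FPKM.

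CDKN1A was at 612 FPKM, CDKN2A at 25.3, CDKN2B at 4.62, RB1 at 11.5, IL6 at 1.36 and IL8 at 4.19, none of them 2-fold from growing, and the BBS7,CCNA2 locus fell to 12.9. In all, 171 genes were at least 2-fold higher and 483 lower, and 26.1% of the changed genes were higher. After rescaling to the same sum 581 were higher and 58.6% of the changed genes were. That share was 27.6% after centring and 30.7% after quantile normalization, so of the 3 rescalings only the same sum turned the direction. The growing library is from day 13, and no empty-vector library of day 3 was analysed here. For every day 3 difference, and for the change from day 3 to day 13, the cleaved histone, recent infection and time in culture therefore cannot be told apart.

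From day 3 to day 13 of H3.3cs1, most matrix and contractile genes and 10 of 20 IGF binding proteins and growth factors rose, while 9 of 17 interferon-stimulated genes and 27 of 34 mitosis genes fell. IGFBP3, which binds insulin-like growth factors, rose 27.8-fold from 35.8 to 1023 FPKM, ANKRD1 rose 25.6-fold, EDN1, the vasoconstrictor endothelin 1, rose 24.2-fold, IGFBP7 rose 19.5-fold to 1661 FPKM and CCND2 rose 18.2-fold. HMOX1 fell 10.7-fold, GPC6, a glypican, 6.72-fold, MME, the peptidase neprilysin, 6.53-fold, BAALC 6.36-fold and SBSN 6.07-fold. Extracellular matrix genes had 15 of 23 higher and 1 lower (median 1.23), contractile genes 10 of 11 higher (median 1.30) and IGF binding proteins and growth factors 10 of 20 higher (median 1.19), each at percentile 100. Matrix proteases had 5 of 16 higher (median 0.47). Interferon-stimulated genes had 9 of 17 lower and 0 higher (median -1.18), and mitosis genes had 27 of 34 lower (median -1.42), as did 10 of 35 replication genes (median -0.77). The unfolded protein list had 2 of 16 higher (median 0.69). The SASP list did not stand apart (median -0.040), with CCL2 (5.62-fold) and IL6 (3.62-fold) higher.

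In this comparison 667 genes were higher and 414 lower. Of the changed genes 61.7% were higher, and 32.1% were after rescaling to the same sum, where 1240 were lower and the median difference of all genes was -0.28. The share was 64.9% after centring and 61.8% after quantile normalization. Of the 171 genes that were higher at day 3 than in growing, 89 then fell and 3 rose further. Of the 483 that were lower, 95 fell further and 137 rose. Both differences use the early library, whose chance values alone produce reversals, so these counts do not show how many genes returned.

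Other lists held close to the growing level or had few members that passed the filter at FPKM of 1. Polycomb genes had medians of 0.050 in OIS, -0.049 in H3.3cs1 late and -0.0021 in early, each with the other sign under at least 1 rescaling, and EZH2, a histone methyltransferase that is also an E2F target, fell 4.31, 5.55 and 3.17-fold. H3.3 genes and chaperones had medians of 0.023, -0.22 and -0.075, with 1 of 9 higher and 1 lower in each, and ASF1B, a histone chaperone, fell from 11.8 FPKM to 0.730, 0.312 and 2.89. Housekeeping genes had medians of 0.051, -0.25 and -0.22 with 0 of 12 past 2-fold. The signs of the H3.3 and housekeeping medians in OIS and in early also turned under at least 1 rescaling. Ribosomal protein genes had medians of 0.33 in OIS and, with a sign that turned on rescaling, -0.23 in early, and 0 of 24 passed 2-fold in either.

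In OIS, p53 targets (median 0.37, 5 of 17 higher and 1 lower), lysosome and autophagy genes (0.35, 3 of 22 higher), interferon-stimulated genes (0.091, 3 of 17 higher and 1 lower), histone genes (-0.14, 5 of 31 higher and 4 lower) and the unfolded protein list (0.21, and -0.021 after rescaling to the same sum) did not stand apart. In H3.3cs1 late, interferon-stimulated genes (median 0.056) and the unfolded protein list (-0.026, and 0.035 after centring) did not either. Of the OIS lists, histone genes did stand apart after rescaling to the same sum (median -0.42) and without a filter on low values, lysosome and autophagy genes after rescaling (0.12) and quantile normalization (0.19), and p53 targets after quantile normalization (0.29). Fibroblast identity genes had a median of -0.30 in H3.3cs1 late, with 1 of 14 higher and 1 lower, and -0.61 in early, with 1 higher and 2 lower, and the late list no longer stood apart after rescaling to the same sum or with a filter at FPKM of 5. At day 3, histone genes (0.38, 4 of 31 higher, and 0.039 and no longer apart without a filter on low values), cholesterol synthesis genes (0.44, 0 of 18 past 2-fold), lysosome and autophagy genes (0.27, 2 of 22 higher) and RAS and MAPK output (-0.42, 1 of 16 lower) stood apart. The SASP list (0.014, 2 of 22 lower), immediate early genes (-0.043) and the inhibitor list (0.070, 1 of 10 lower) did not at day 3, and the first 2 of these medians changed sign with scaling.

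Of markers of other cell types, 5 of 12 epithelial genes passed the filter. They had medians of -0.48 in OIS, 0.38 in H3.3cs1 late and 0.53 in early, with 2 lower, 2 higher and 2 higher. KRT18, a keratin, was at 80.0 FPKM in growing, 13.1 in OIS, 50.9 in early and 170 in late. The early list stood apart, and no longer did without a filter on low values or with a filter at FPKM of 5. The endothelial list in OIS likewise no longer stood apart with a pseudocount of 0.1 or a filter at FPKM of 5, and its medians in H3.3cs1 late and early were -0.40 and -0.060, the latter above 0 after rescaling to the same sum. Of 12 leukocyte markers 1 passed the filter, in the joined locus CD68,MPDU1, at 56.2 FPKM in growing, 89.4 in OIS, 52.3 in early and 39.3 in late.

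In both OIS and H3.3cs1 late all 34 mitosis genes fell against growing. Set against each other, 19 of 22 SASP genes were higher in OIS than in H3.3cs1 late, and 9 of 11 contractile and 15 of 23 matrix genes were lower. Lower in both against growing were 351 genes, 52.6% of those lower in H3.3cs1 late, with UBE2C, CDC20, TOP2A, PLK1, CDK1, KIF20A, LMNB1, NUSAP1, PBK and BIRC5 the furthest. Higher in both were 67 genes, 15.7% of those higher in H3.3cs1 late. They were led by CYP26B1 (6.16-fold in OIS, 6.65-fold in late), which degrades retinoic acid, CDKN2B, MYOZ2 (4.61 and 6.13-fold), L1CAM (4.30 and 6.53-fold), a cell adhesion molecule, and ANGPTL4 (3.98 and 3.92-fold), with SERPINE2, VCAM1, QPRT, USP53 and CLDN1 next. Opposite were 58 genes higher in OIS and lower in late, such as LCE2A, NTSR1, STC1, KCNG1 and MMP1, and 77 lower in OIS and higher in late, such as ANKRD1, CPA4, MAMDC2, EDN1 and PRPS1.

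Independent lists of these sizes would share 54.5 lower and 39.1 higher genes, and simulated unchanged groups with a shared control shared 2.04 and 2.13 on average. Independent lists would put 60.9 and 35.0 genes in the opposite classes. Across genes, which are not independent replicates, differences of OIS and H3.3cs1 late from growing had a Pearson r of 0.26 and a Spearman rho of 0.16, against a mean r of 0.50 for simulated unchanged groups. Their covariance was 0.18 against a simulated 0.059. The simulated r lies near 0.50 by construction, because every simulated library had noise of the same size and 1 control was shared. It is therefore no mark of how alike unchanged real groups would be. OIS minus growing and H3.3cs1 late minus H3.3cs1 early, which share no library, had an r of -0.029, with 136 genes lower in both against 33.8 for independent lists and 69 higher in both against 60.9. Late minus early leaves out differences present at day 3, when the mitosis median against growing was -2.003, against -3.46 in late. It also counts the low day 3 values of matrix and contractile genes as rises. An r near 0 there does not show that OIS and late differ from growing in unlike ways. The simulated noise leaves out extreme values and values wrongly listed at 0, and with it few unchanged genes pass 2-fold. The simulated overlap is therefore small by construction, and the simulated covariance may be too small. Neither shows how much of the overlap or covariance the shared library gives. With 1 growing library the control could not be split, and part of the overlap may come from it.

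**Figure D3:**
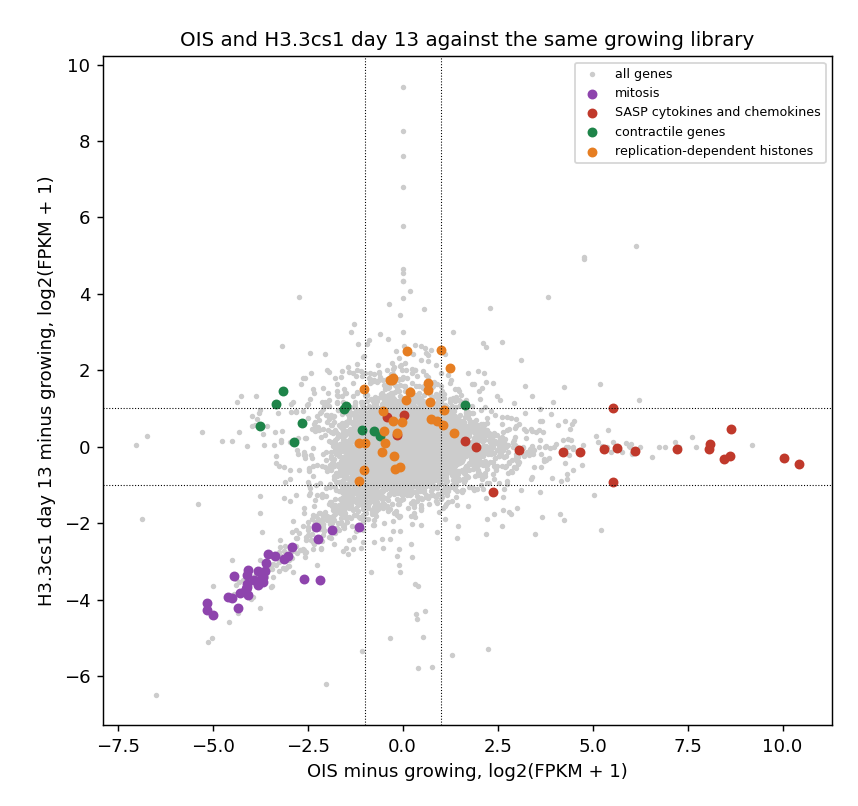
Difference from the growing library in OIS (x axis) and in H3.3cs1 late (y axis), both in log2(FPKM + 1), with 1 point per gene, 4 gene lists in colour and dotted lines at 2-fold. Mitosis genes lie low on both axes, and most SASP genes spread along the x axis, up to 10.44, near 0 on the y axis.

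Compared directly, IL8 was 1890.2-fold, IL1B 1291-fold, MMP3 562-fold, CXCL5 471-fold and CXCL1 440-fold higher in OIS than in H3.3cs1 late, and ANKRD1 (98.3-fold), CPA4 (56.8-fold), a carboxypeptidase, OXTR (45.6-fold), the oxytocin receptor, KISS1 (30.3-fold) and MAMDC2 (29.8-fold) were lower. Of the SASP list 19 of 22 were higher and 1 lower (median 5.52), of matrix proteases 10 of 16 were higher and 2 lower (median 2.16), of RAS and MAPK output 11 of 16 (median 2.54) and of immediate early genes 9 of 14 (median 1.31). Contractile genes had 9 of 11 lower (median -2.55), extracellular matrix genes 15 of 23 lower and 4 higher (median -1.58), with LOX 13.3-fold and LUM 10.2-fold lower and COL6A3 8.83-fold higher, and histone genes 12 of 31 lower and 1 higher (median -0.81). Replication genes did not stand apart (median 0.0025, below 0 under each rescaling), and mitosis genes lay lower in OIS (median -0.39) with PLK1 and CCNB2 lower and MAD2L1, a spindle checkpoint protein, 2.49-fold higher. Ribosomal protein genes had a median of 0.82 with 3 of 24 higher. In all, 1363 genes were higher and 1037 lower in OIS, and 111 of them were listed at 0 in one of both libraries. Of the changed genes 56.8% were higher. That share was 39.7% after rescaling to the same sum, where the median of all genes moved from 0.092 to -0.13, 48.5% after centring and 49.4% after quantile normalization, so which direction prevailed depended on the scaling.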

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

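All 3 patterns weighed here were picked after the results had been seen, and the test of S phase, the question of retroviral infection and the choice of RMRP and RPPH1 also came after the values they rest on. The other tests were written down before they were run. The differences between groups in this part were not tested, because each group has 1 library.

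The medians of matrix and contractile genes lay on opposite sides of growing in OIS and H3.3cs1 late. The median of the contractile list was -2.55 and that of the extracellular matrix list -1.58 for OIS against H3.3cs1 late. Scaling between libraries is argued against, since over 3 rescalings the joint median of both lists stayed at -1.26 or below in OIS and at 0.49 or above in late. Mature smooth muscle cells in the late library are argued against by MYH11 at 0.627 FPKM and DES at 0.195. That 79.4% of the 34 members lay below 0 in OIS and 85.3% above 0 in late follows in part from the medians and decides nothing about single genes. At day 3 of H3.3cs1 the medians were -0.82 for matrix and -0.61 for contractile genes, and the differences in construct, vector, tamoxifen and days stay open.

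Replication-dependent histone genes stood above growing in H3.3cs1 late, with a median of 0.68. A larger share of cells in S phase is argued against by DNA replication genes, whose median was -1.99 in the same comparison, and scaling by a histone median of at least 0.69 over 3 rescalings. RNA without a poly(A) tail carried into the late library cannot be told apart. The 86 loci for small RNAs made without such a tail had a median difference of 0, under the bound written to exclude it, but that bound was wrong, because their spread of 1.37 (scaled median absolute deviation), with 38 above and 33 below 0, is wider than the histone median, and RMRP (16.1 FPKM in growing, 16.2 in late) and RPPH1 (3.60 and 2.53) are too few to decide. Histone transcripts with poly(A) tails, as in cells that have left the cycle, are a candidate explanation that these values per gene do not test.

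Interferon-stimulated genes stood above growing at day 3, with a median of 0.86, and near it at day 13. Leukocytes in the early library are argued against by PTPRC, LYZ, CD14 and TYROBP, the highest at 0.145 FPKM, and scaling by a list median of at least 0.88 over 3 rescalings. Recent retroviral infection and the cleaved histone cannot be told apart, because no empty-vector library of day 3 was analysed here, and the median of 0.056 at day 13 goes with either.

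From day 3 to day 13 of H3.3cs1 the medians of 3 lists moved from below to above the growing level, with differences of 1.19 for IGF binding proteins and growth factors, 1.23 for extracellular matrix and 1.30 for contractile genes. Single genes with opposite changes of at least 2-fold in OIS and H3.3cs1 late differed between those libraries by 7.40 (STC1), 6.16 (MMP1), 5.75 (LCE2A), 4.68 (KCNG1) and 4.48 (NTSR1) in one direction, and by -6.62 (ANKRD1), -5.83 (CPA4), -4.90 (MAMDC2), -4.46 (EDN1) and -3.99 (PRPS1) in the other, on the log2 scale. Loci with no gene name, outside every comparison above, held values at least 2-fold above growing at 269 loci in OIS, 48 in H3.3cs1 early and 220 in H3.3cs1 late, and at least 2-fold below it at 123, 75 and 75, of 1389 that reached an FPKM of 1 in a library.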

How the results depend on the processing

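Keeping the highest line per symbol and leaving out joined loci were chosen after the data were seen, and the other 7 alternatives were planned. Under all 9 alternatives the mitosis and replication lists lay below their random lists in OIS, H3.3cs1 late and early against growing, and the SASP list above them in OIS and within their range in late and early. The place of the SASP list in late and early is limited by members, such as IL1A, that were below 1 FPKM outside OIS. Mitosis medians ran from -5.22 to -3.77 in OIS and -4.32 to -3.42 in late, and SASP medians from 5.28 to 6.92 in OIS and -0.27 to -0.058 in late. Counts, the covariance and the correlations are taken as held when within 1.5 times the reported value (or when both correlations lie within 0.1 of 0), percentages of changed genes when inside the 95% binomial interval of the reported one, and list medians when they keep their place inside or outside the range of random lists. By that measure 232 of the values that answer a comparison held and 29 moved, 11 with a pseudocount of 0.1 and 9 after rescaling to the same sum. The binomial interval treats genes as independent, which they are not, so it is a yardstick and not a measure of spread. The correlation of OIS and H3.3cs1 late ranged from 0.25 to 0.27.

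With a pseudocount of 0.1, which lets low genes pass the size rule, 1523 genes were lower in OIS (48.9% of the changed genes higher), 743 higher in H3.3cs1 late (43.4%), 437 higher in H3.3cs1 early (38.5%) and 910 lower from day 3 to day 13 (50.6% higher), and 53.1% were higher in OIS against late. The genes higher in both OIS and late were 208 and the covariance was 0.36. With named genes rescaled to the same sum, which moves the median of all genes and makes the pseudocount smaller beside the values, 1768 genes were lower in OIS (36.9% higher), 43.6% were higher in H3.3cs1 late, 581 higher in H3.3cs1 early (58.6%), 1240 lower from day 3 to day 13 (32.1% higher) and 1886 lower in OIS than in H3.3cs1 late (39.7% higher). The percentage higher was 49.0 in OIS, 43.8 in late, 64.9 from day 3 to day 13 and 48.5 in OIS against late after centring, 50.1, 45.1 and 30.7 in OIS, late and early and 49.4 in OIS against late after quantile normalization, and 21.3 in early with a filter at FPKM of 5. Beyond what these constructions show, the cause was not tested.

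Of the other list medians, 1006 held, 23 no longer stood apart, 9 newly did and 1 turned, the epithelial markers from day 3 to day 13 (0.56), to -0.17 after rescaling to the same sum, and the cause was not tested. No alternative changed the sign of a named difference of at least 2-fold, and of 416 such differences 19 fell below 2-fold under quantile normalization, 17 after rescaling, 9 after centring and 1 with the highest line per symbol. No paired analysis was possible because each group has 1 library. Depth was estimated only relative to growing, and roughly. If the weak estimate of 77.6% for H3.3cs1 late holds, it limits what can be read from the low values of that library.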

Other observations

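The genes in this paragraph were picked after their values were seen. The 3 collagen VI genes stood above growing in OIS, where the type I collagen gene COL1A1 fell, and below it in H3.3cs1 late. COL6A2 rose 2.58-fold in OIS to 2818 FPKM, while COL6A1 (1816 against 938 in growing) and COL6A3 (1018 against 538) stayed within 2-fold. In H3.3cs1 late COL6A3 fell to 114 FPKM, and COL6A1 and COL6A2 were at 474 and 638. PRRX1, a mesenchymal transcription factor, was at 22.8 FPKM in growing, 15.6 in OIS and 19.1 in H3.3cs1 early, and fell 6.28-fold to 2.79 in H3.3cs1 late. HMGA1, a chromatin architecture protein, was at 667 FPKM in growing, 1287 in OIS and 414 in early, and fell 3.26-fold to 204 in late.

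The question below was asked after ANKRD1, CTGF, TGFB2 and IGFBP3 had been seen and its test was written before it was run. It was asked whether targets of the coactivators YAP and TAZ lie above growing in H3.3cs1 late, as the medians of the matrix and contractile lists did. The 18 other members of a list of YAP and TAZ targets had a median of 0.012 against growing, at percentile 66.3 of random lists, with 2 higher and 0 lower. These 18 as a set therefore did not stand above growing. The full list of 22, with the genes that prompted the question, had a median of 0.18 (percentile 97.7, 6 higher and 0 lower). That placement stands apart but rests in part on genes already seen to rise. Of the 18 members, 7 were higher and 0 lower from day 3 to day 13 (median 0.44, percentile 99.7), and their median in OIS was -0.69.

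A test was set, before it was run, on whether proliferation genes carry the similarity of OIS and H3.3cs1 late, from the relation that shares no library. Its r was -0.029 over all genes and -0.061 without the 87 genes of the mitosis, replication and lamina lists, and with a starting value so near 0 the test decides nothing. The counts that follow were added after the results had been seen. In that relation 136 genes were lower in both, 39 on those lists and 97 outside, against 28.3 outside for independent lists. Of the 351 genes lower in both against growing, 74 were on the lists (85.1% of their genes) and 277 outside (2.29% of the other 12095 genes), against 44.6 outside for independent lists. The lists do not hold every proliferation gene, and the second count shares the growing library, so whether proliferation genes account for the shared falls stays open.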
